A study of Mus musculus with 9 samples.

How the data were processed

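RNA from 9 cultures of a mouse pancreatic cancer cell line, grown in monolayer, was labelled with a 3′ IVT kit and hybridised to Affymetrix expression arrays, per the labels' protocols. The labels give 3 groups by stable transfection (control, beta-catenin, ICAT) with 3 replicates each. The deposited values are log2 expression, 1 value per probe set and array, made by the authors with RMA from the affy package, per the submitters' processing notes. RMA corrects background, normalizes the arrays to the same distribution and summarises the probes of a set. Versions are not given in the sources used here, and scanner files were not used here. RMA compresses differences of dim probe sets, and its normalization assumes that arrays have similar distributions, so a shift of all genes in one direction would not be seen. Affymetrix control probe sets were not analysed here, so RNA quality was not tested.

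The table holds 45037 probe sets. By the platform annotation 34945 have 1 gene symbol, 932 several and 9160 none. Symbols were updated through Entrez identifiers in a RefSeq gene table, which held all but 204 of the single-gene probe sets, and the annotation's own symbol was kept for those. A gene was represented by the probe set with the highest mean over all 9 arrays among its single-gene probe sets, which gave 18193 genes. Genes with log2 expression of at least 5 on at least 3 arrays were kept, 15235 in all. Other probe sets of the named genes were fitted in a separate model over all probe sets. One called in the opposite direction is given with the gene. Other probe sets that were merely not called are not always mentioned. The 9 arrays were compared before use, and no 2 were identical. Gene positions on assembly GRCm38.p6 in the gene table served only to order neighbouring genes for the closing section, and none is printed.

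One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (6 residual and 5.03 prior degrees of freedom). Beta-catenin against control, ICAT against control and beta-catenin against ICAT were tested by moderated, two-sided tests with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05. No block for the replicate number was used, because no label says that a number marks a shared day or culture. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1, so single values have no such test.

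The design, the tests, the rule for naming genes, the alternatives and 27 gene lists were fixed before the data were examined. The lists were Wnt/beta-catenin target genes, Wnt pathway components, YAP/TEAD target genes, G1/S and DNA replication genes, G2/M and mitosis genes, epithelial junction and keratin genes, mesenchymal and EMT genes, matrix remodelling enzymes and inhibitors, integrins and basement membrane genes, fibroblast markers, immune and endothelial markers, acinar, ductal and endocrine genes, stem cell markers, hypoxia and glycolysis genes, interferon-stimulated genes, MHC class I genes, NF-kB and inflammatory genes, Notch, Hedgehog and TGF-beta/BMP genes, immediate-early and MAPK feedback genes, unfolded protein and stress response genes, p53 target genes, cholesterol genes, and semaphorin, ephrin and axon guidance genes. Lists were tested with camera (preset correlation of 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry.

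Named genes were, for each comparison with control, the 10 with the largest increase and the 10 with the largest decrease among called genes whose treated arrays all lay on one side of the control arrays. For beta-catenin against ICAT 5 each way were taken. Clone names and Xist were left out of this rule. To these were added the 10 largest opposite-direction and 6 largest same-direction genes, Ctnnb1, Ctnnbip1, Axin2, Lef1, Ccnd1, Myc, Ccn1, Cdh1 and Vim, and up to 4 called members of each list. The rule ranked deposited values, including those under the filter, which have no sure order. For a printed fold, arrays under log2 5 in a group whose mean lay under 5 were set to 5, and the fold is a lower bound. The deposited table used here has no detection calls, so 5 is a chosen limit and not a measured background. Not every gene the rule selects is described.

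The scripts were tested on simulated data with the control means and, for each gene, 1 spread shared by all groups. Real ICAT arrays varied more than control arrays (median SD 0.121 against 0.0567). The simulated false calls therefore do not show the error under unequal spread. For beta-catenin against control, run on 15235 genes, 18 percent of genes changed 1.2-fold and 100 percent of those changed 1.5-fold were recovered, with 5.36 percent false calls. For ICAT against control, also on 15235 genes, 28 and 96 percent were recovered, with 3.57 percent false calls. Overlap expected from the shared controls was simulated 100 times. Alternatives were no filter, a filter at log2 7, the mean of a gene's probe sets, repeated quantile normalization, median centring, limma's trended robust moderation, only the 6 arrays compared, array weights, a replicate block, each array left out, every probe set of the transfected genes and a 2-fold threshold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.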

Results

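The expression of genes was measured in a mouse pancreatic cancer cell line after stable transfection. One group carried a control, one beta-catenin (Ctnnb1), the transcriptional co-activator of the Wnt pathway, and one ICAT (Ctnnbip1), a small protein that binds beta-catenin and blocks its binding to TCF factors. There were 3 arrays per group, 9 in all, described in the labels as independent or biological replicates. Each array gave a log2 expression value for 45037 probe sets, and array medians lay between 6.21 and 6.29. After 1 probe set was chosen per gene and low values were filtered, 15235 genes were tested with limma. Arrays of a group correlated at 0.998 or higher for control cells, 0.997 or higher for beta-catenin cells and 0.9908 or higher for ICAT cells. The median SD per gene between replicates was 0.0567 in control, 0.0746 in beta-catenin and 0.121 in ICAT cells on the log2 scale, so ICAT values carried the largest error. The labels do not say whether the samples of a group came from separate transfections, and p-values measure only the spread between these samples. With 3 arrays per group, their number limits the precision. Below, "rose" and "fell" are relative to the second group of a comparison, folds come from differences of mean log2 values with n = 3 per group, and adjusted p-values of single genes are from limma. Where a group's mean lay under the filter of log2 5, its arrays below 5 were set to 5 and the fold is given as "at least".

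The transcripts of the transfected genes differed little between the groups. Ctnnb1 had a mean log2 expression of 12.68 ± 0.0136 (SD, n = 3) in control, 12.88 ± 0.0146 in beta-catenin and 12.88 ± 0.107 in ICAT cells. It was 1.15-fold higher in beta-catenin cells (limma, adjusted p = 0.0353) and 1.14-fold higher in ICAT cells (adjusted p = 0.0364). The beta-catenin call was lost when any 1 of the 3 control or 3 beta-catenin arrays was left out (adjusted p from 0.0664 to 0.104). The ICAT call was lost without control replicate 1, 2 or 3, beta-catenin replicate 2 or 3, or ICAT replicate 1 or 2 (adjusted p from 0.0521 to 0.11). Both other Ctnnb1 probe sets were above control in beta-catenin cells by 0.26 and 0.18 on the log2 scale without passing the test (adjusted p = 0.0904 and 0.0744 in a fit over all probe sets). In that fit the brightest probe set, used above, did not pass either (adjusted p = 0.0672 in beta-catenin and 0.0702 in ICAT cells). In ICAT cells the other probe sets were above control by 0.17 and 0.25, and the second passed (adjusted p = 0.304 and 0.0162 over all probe sets). Ctnnbip1 was 1.10-fold above control in ICAT cells (log2 8.79 ± 0.151 against 8.65 ± 0.0266, adjusted p = 0.189) and did not pass the test by its other probe set either (adjusted p = 0.58). Probe sets of this array type lie near the 3′ end of a transcript, and a transfected coding sequence without that end would not be seen by them, so these values check neither the transgenes nor the labels.

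**Figure D1:**
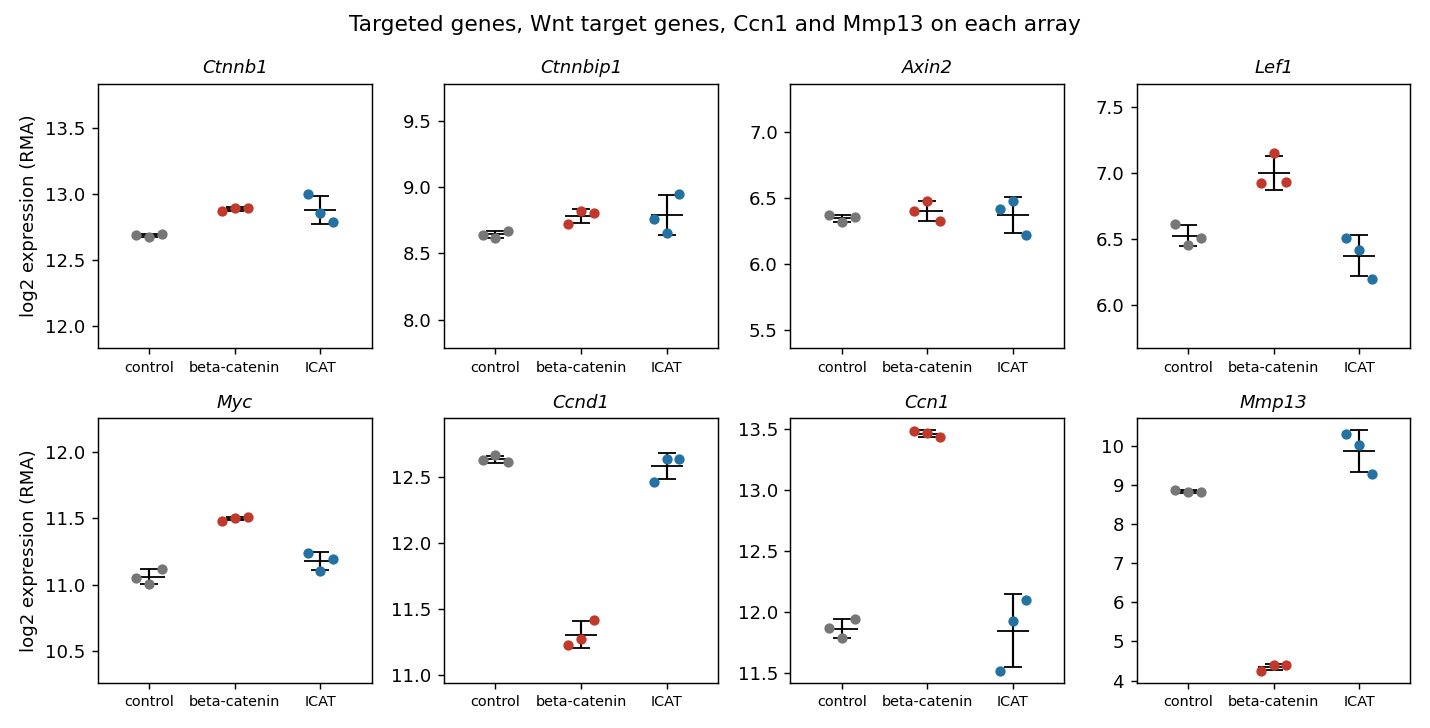
Log2 expression (RMA, vertical axes) of 8 genes in control, beta-catenin and ICAT cells; each point is 1 array, horizontal bars are means and error bars are SD (n = 3). The axes do not start at 0 and differ in range; Ccn1 in beta-catenin cells lies above all other arrays (13.46 against 11.87 in control), and Mmp13 is lowest in beta-catenin cells (4.35) and highest in ICAT cells (9.88).

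Known target genes of beta-catenin moved in different directions. Lef1, a TCF-family factor and Wnt target, rose 1.39-fold in beta-catenin cells (adjusted p = 0.00181), and Myc rose 1.36-fold (adjusted p = 0.000178). Ccnd1, which encodes cyclin D1, fell 2.51-fold (adjusted p = 1.21e-07). Axin2, a commonly used readout of Wnt signalling, lay at 6.35 in control, 6.40 in beta-catenin and 6.37 in ICAT cells and passed the test in neither line (adjusted p = 0.646 and 0.843). In ICAT cells Lef1 (log2 difference -0.15, adjusted p = 0.246), Myc (0.12, adjusted p = 0.156) and Ccnd1 (-0.05, adjusted p = 0.635) did not pass. Of 21 tested Wnt/beta-catenin target genes, 3 rose and 5 fell in beta-catenin cells, and 2 rose and 2 fell in ICAT cells. The list was called in neither comparison by camera (adjusted p = 0.236 and 0.663; 0.563 and 0.75 with an estimated correlation). Fst, which encodes the activin-binding protein follistatin, and Apcdd1, which encodes an inhibitor of Wnt signalling, fell in both lines. Fst fell 27.5-fold with beta-catenin and 2.77-fold with ICAT, and Apcdd1 3.64-fold and 2.6-fold. Vim fell 1.38-fold in beta-catenin cells (adjusted p = 9.37e-05) and did not pass in ICAT cells (adjusted p = 0.253). Cdh1 was not tested, because its highest value on any array was 3.56, under the filter of 5.

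Beta-catenin cells against control cells. The keratinocyte envelope gene Sprr1b rose at least 23-fold in beta-catenin cells, from a mean log2 expression of 4.53 ± 0.0355 (SD, n = 3) to 9.53 ± 0.155 (adjusted p = 1.01e-09). Increases of similar size were seen for the matrix protein gene Tgfbi (23.2-fold), the chemokine gene Cxcl12 (22.1-fold), the kinase gene Dclk1 (21.7-fold) and the matrix glycoprotein gene Thbs1 (17.6-fold). The urea transporter gene Slc14a1 fell 61.9-fold, from 11.49 ± 0.0699 to 5.54 ± 0.316 (adjusted p = 4.98e-10). The growth factor gene Bmp2 fell 50-fold, the secreted Wnt modulator gene Dkk2 37.5-fold, the collagenase gene Mmp13 at least 14.4-fold and the apolipoprotein gene Apoc2 22.2-fold. In all, 5321 genes passed an adjusted p of 0.05 (limma), 2981 higher and 2340 lower, and 704 of them changed at least 2-fold, 458 higher and 246 lower. With array weights, which favoured beta-catenin replicate 2 most and ICAT replicate 3 least, 8324 genes passed. With only the 6 beta-catenin and control arrays fitted, 6658 genes passed.

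Further genes among the largest increases were Nrep (at least 21.7-fold), the heparan sulfate sulfotransferase gene Hs6st2 (19.1-fold), the glutathione transferase gene Mgst1 (18.2-fold), the pentraxin gene Ptx3 (17.3-fold) and Trim44 (17.2-fold). Among the largest decreases were Bhlhb9 (at least 13.3-fold), the claudin gene Cldn6 (18-fold), the cannabinoid receptor gene Cnr1 (13.0-fold) and the protocadherin gene Pcdh17 (at least 12.2-fold). All of these had 3 beta-catenin arrays on one side of the 3 control arrays, as the rule for naming genes required. So did 54.1 percent of all tested genes. Ccn1, also called Cyr61, which encodes a matricellular protein and is a target of YAP, rose 3.01-fold from 11.87 ± 0.0784 to 13.46 ± 0.0277 (adjusted p = 1.33e-06). Its 3 other probe sets rose too, by 1.66-fold to 2.92-fold.

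Immediate-early and MAPK feedback genes, which are induced by growth factor signalling and in part restrain it, fell as a list in beta-catenin cells. Of 26 tested members 19 fell and 3 rose, with a median log2 difference of -0.69 (camera, adjusted p = 2.31e-07; adjusted p = 0.501 with an estimated correlation). Spry4 fell 8.46-fold, Etv5 7.20-fold, the epiregulin gene Ereg 5.88-fold and Dusp4 5.11-fold. Hypoxia and glycolysis genes fell, with 13 of 23 members lower and 2 higher (15 and 2 adjusted over the list alone; camera, adjusted p = 0.00116; adjusted p = 0.565 with an estimated correlation). Adm, which encodes adrenomedullin, fell 3.32-fold and the glucose transporter gene Slc2a1 3.20-fold, while the phosphofructokinase gene Pfkp rose 3.42-fold and Pfkfb3, whose product makes an activator of phosphofructokinase, 2.83-fold. Integrins and basement membrane genes fell, with 10 of 24 lower and 2 higher (10 and 3 adjusted over the list alone; camera, adjusted p = 0.00951; adjusted p = 0.501 with an estimated correlation). Itgb8 fell at least 3.67-fold and Itga6 3.70-fold, and Col4a5 rose 3.02-fold and Itgb5 2.48-fold.

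Interferon-stimulated genes rose in beta-catenin cells, with 14 of 24 members higher and the others not called (median log2 difference 0.86; camera, adjusted p = 0.000141; adjusted p = 0.563 with an estimated correlation). The guanylate-binding protein genes Gbp2 and Gbp3 rose 6.23-fold and 4.98-fold, Xaf1 4.08-fold and Rtp4 2.98-fold. MHC class I and antigen processing genes rose, with 8 of 12 higher and the others not called (camera, adjusted p = 0.00494; adjusted p = 0.563 with an estimated correlation), led by the immunoproteasome gene Psmb8 (3.88-fold). The MHC class I call was lost with a stricter filter of log2 7 on 3 arrays (adjusted p = 0.0559). Fibroblast markers had 5 of 12 members higher and 2 lower and were not called (camera, adjusted p = 0.236), with Pdgfra 4.11-fold higher and Col1a2 2.63-fold lower. Control cells themselves expressed Col1a2 strongly (log2 12.17), though Postn was dim (5.49). The list therefore does not by itself mark another cell type here. Among immune and endothelial markers 4 of 13 were lower and none was higher by limma, nor at an unadjusted p of 0.05 (camera, adjusted p = 0.0597).

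The other lists were not called in beta-catenin cells. Wnt pathway components had 20 of 48 members higher and 6 lower (23 and 6 adjusted over the list alone; camera, adjusted p = 0.0596). The receptor gene Fzd6 rose 5.20-fold and Wnt4 2.62-fold, and Ror1 fell 2.51-fold. YAP/TEAD target genes had 11 of 22 higher and 4 lower (13 and 4 adjusted over the list alone; camera, adjusted p = 0.0902), with Tgfb2 5.81-fold higher and Igfbp3 at least 5.57-fold lower. Matrix remodelling enzymes and inhibitors went both ways, with 11 of 23 higher and 8 lower (camera, adjusted p = 0.755). Mmp3 fell 11.8-fold and Mmp10 8.10-fold, and Adamts5 rose 3.83-fold. Mesenchymal and EMT genes had 7 of 20 higher and 7 lower (7 and 8 adjusted over the list alone; camera, adjusted p = 0.884), with the matrix gene Tnc 10.5-fold and the gelatinase gene Mmp2 7.07-fold higher and the transcription factor gene Foxc2 4.77-fold lower. Semaphorin, ephrin and axon guidance genes had 7 of 33 higher and 9 lower (7 and 10 adjusted over the list alone; camera, adjusted p = 0.293), with Sema6d 7.63-fold and Sema3a 5.70-fold lower. NF-kB and inflammatory cytokine genes had 10 of 26 higher and 2 lower (11 and 2 adjusted over the list alone; camera, adjusted p = 0.0608), with Il6 at least 4.48-fold higher.

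G1/S and DNA replication genes had 7 of 25 higher and 5 lower in beta-catenin cells (camera, adjusted p = 0.93), and G2/M and mitosis genes 5 of 26 higher and 3 lower (adjusted p = 0.351). TGF-beta and BMP response genes had 11 of 25 higher and 5 lower (12 and 5 adjusted over the list alone; camera, adjusted p = 0.0597). Notch pathway genes had 5 of 17 higher and 3 lower (5 and 4 adjusted over the list alone; camera, adjusted p = 0.592), and Hedgehog pathway genes 4 of 14 higher and 2 lower (adjusted p = 0.236). Stem and tumour-initiating cell markers had 5 of 17 higher and 5 lower (6 and 6 adjusted over the list alone; camera, adjusted p = 0.884). For p53 target genes the counts were 7 of 16 higher and 3 lower (7 and 5 adjusted over the list alone; camera, adjusted p = 0.292). Unfolded protein and integrated stress response genes had 2 of 23 higher and 5 lower (camera, adjusted p = 0.802), and cholesterol biosynthesis and uptake genes 5 of 16 higher and 3 lower (adjusted p = 0.755). Epithelial junction and keratin genes had 1 of 23 higher and 3 lower (camera, adjusted p = 0.755). Ductal and pancreatic progenitor genes had 2 of 16 higher and 1 lower (adjusted p = 0.992), acinar cell genes 1 of 12 higher and 1 lower (adjusted p = 0.884), and endocrine and neuroendocrine genes 1 of 11 higher and 1 lower (adjusted p = 0.884). The lower acinar and endocrine calls were not made when adjusted over the list alone, and counts given without a second pair were the same adjusted over the list alone.

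**Figure D2:**
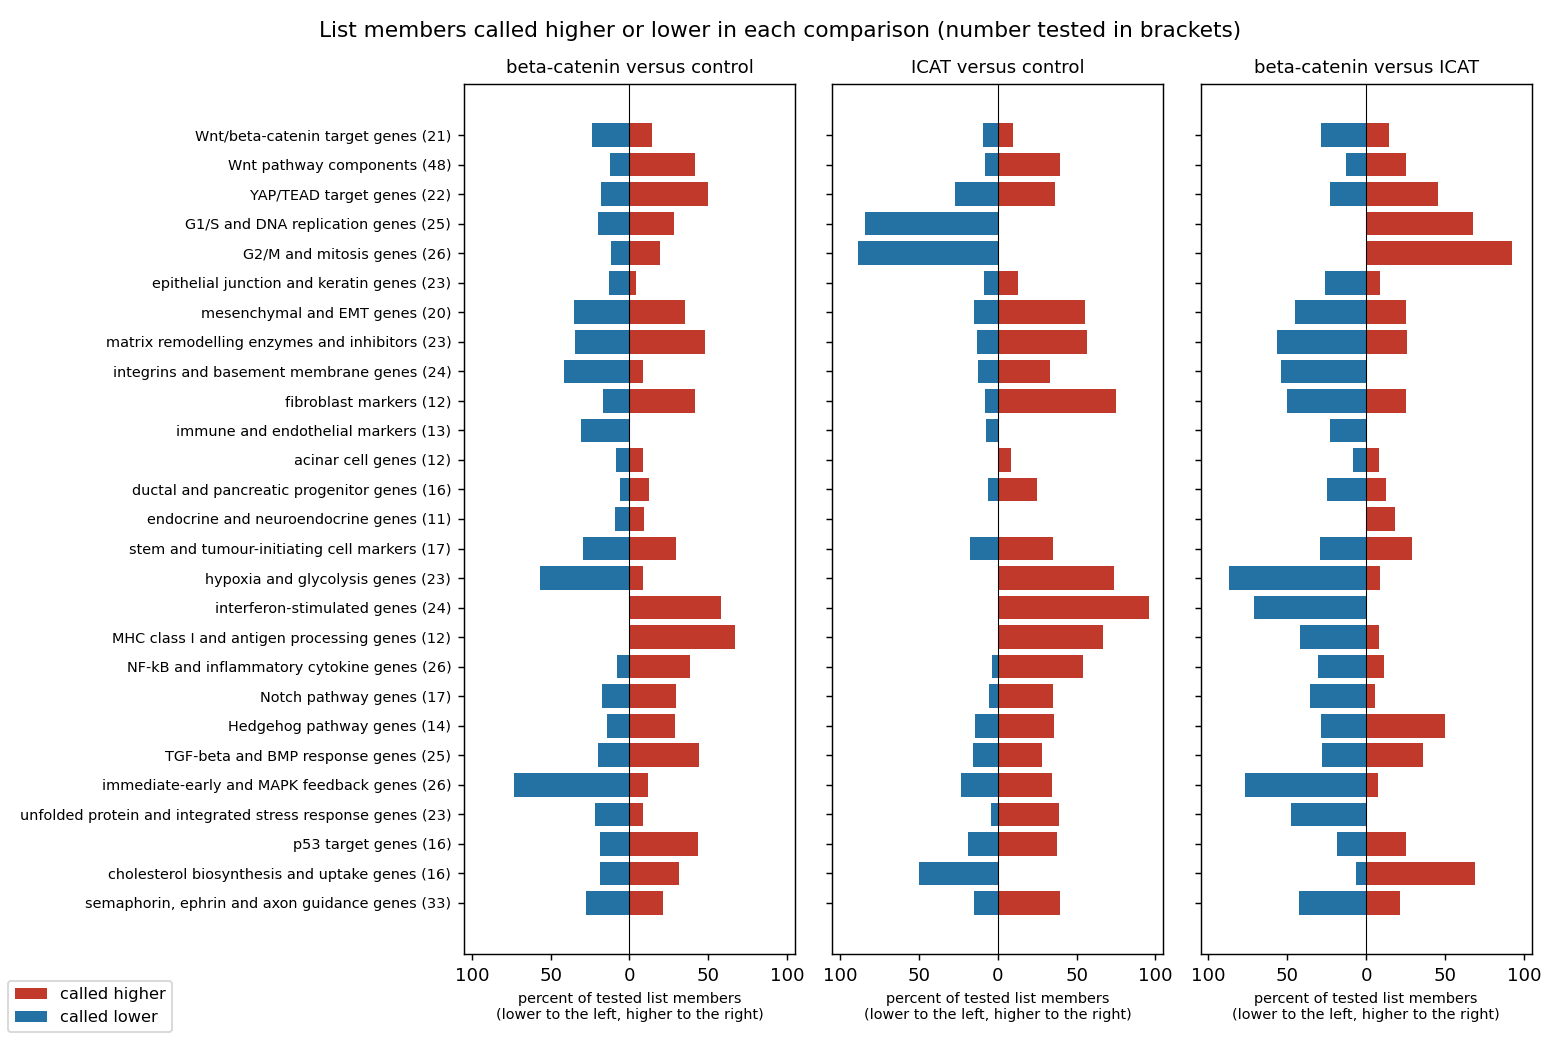
Percent of the tested members of each of the 27 gene lists (rows, number tested in brackets) that passed the limma threshold higher (red, to the right) or lower (blue, to the left) in each of the 3 comparisons; the horizontal axes run from 0 to 100 percent on either side. The hypoxia and glycolysis list lies mostly to the left for beta-catenin against control (13 of 23 lower) and to the right for ICAT against control (17 of 23 higher).

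ICAT cells against control cells. The metalloreductase gene Steap4 rose at least 29.1-fold in ICAT cells, from 4.91 ± 0.0828 (SD, n = 3) to 9.86 ± 1.21 (adjusted p = 1.06e-05; at least 18.1-fold without ICAT replicate 1), and Mgp, which encodes matrix Gla protein, rose 26.3-fold, from 6.62 ± 0.0353 to 11.34 ± 0.64. The tubulin gene Tubb2b rose at least 11.8-fold, the complement protease gene C1s1 11.2-fold, the peptidase gene Mme at least 6.07-fold and Ptx3 10.1-fold. Apoc2 fell 22.1-fold, from 9.60 ± 0.0536 to 5.13 ± 0.154 (adjusted p = 2.28e-10), and the phosphatase gene Inpp4b fell 4.72-fold. In all, 5670 genes passed (limma), 2850 higher and 2820 lower. The model shared its estimate of spread over all groups, although ICAT arrays varied most. With only the 6 ICAT and control arrays fitted, 5079 genes passed. Changes of at least 2-fold were mostly increases, with 379 genes higher and 69 lower, 448 together.

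Other large increases in ICAT cells were those of Cyp7b1, which encodes an oxysterol hydroxylase (at least 4.51-fold), Mgst1 (8.78-fold), Bst1 (8.59-fold) and Usp18, which encodes a protease that removes ISG15 (at least 7.89-fold). A further probe set of Cyp7b1, under the filter in every group, was called in the opposite direction (adjusted p = 0.0171 over all probe sets). The largest decreases after Apoc2 and Inpp4b were those of the receptor gene Calcrl (at least 3.28-fold), Ccbe1 (4.06-fold), the anion transporter gene Slco4a1 (3.57-fold), the ribosome biogenesis gene Nop16 (3.46-fold), Kctd4 (3.20-fold), the RNA polymerase I factor gene Taf1d (3.09-fold), the phosphatase gene Dusp9 (3.08-fold) and Fst (2.77-fold). In this comparison no other probe set was called for Ptx3, Mgst1, Inpp4b, Calcrl or Nop16. The Ccn1 probe sets disagreed. The brightest did not pass (log2 difference -0.02, adjusted p = 0.941), whereas 2 of the other 3 were 2.18-fold lower (adjusted p = 0.00111 and 0.00315 over all probe sets).

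Interferon-stimulated genes rose in ICAT cells, with 23 of 24 members higher and the other not called (median log2 difference 1.78; camera, adjusted p = 3.04e-13; adjusted p = 0.27 with an estimated correlation). Usp18 rose at least 7.89-fold, Rtp4 8.13-fold, Xaf1 7.66-fold and Ifit1 6.99-fold. MHC class I and antigen processing genes rose, with 8 of 12 higher and the others not called (camera, adjusted p = 3.23e-05; adjusted p = 0.27 with an estimated correlation), among them Psmb8 (3.93-fold) and the tapasin gene Tapbp (2.27-fold). NF-kB and inflammatory cytokine genes rose, with 14 of 26 higher and 1 lower (15 and 1 adjusted over the list alone; camera, adjusted p = 2.63e-05; adjusted p = 0.378 with an estimated correlation), such as Il33 (at least 1.58-fold) and Ccl2 (3.14-fold). Il6 rose at least 3.84-fold, with an SD of 1.49 between the ICAT arrays, and at least 2.12-fold without ICAT replicate 1. Beside these lists, fibroblast markers were higher (9 of 12). Immune and endothelial markers had 1 of 13 lower and none higher by limma (1 higher at an unadjusted p of 0.05; camera, adjusted p = 0.817), and the lower one did not pass when adjusted over the list alone.

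Genes of the cell cycle fell in ICAT cells. Of 26 G2/M and mitosis genes 23 fell (26 adjusted over the list alone) and none was higher at an adjusted p of 0.05 (median log2 difference -0.52; camera, adjusted p = 4.42e-10; adjusted p = 0.408 with an estimated correlation). The mitotic kinase genes Aurka and Plk1 each fell 1.83-fold, and Ube2c fell 1.66-fold. Of 25 G1/S and DNA replication genes 21 fell (22 adjusted over the list alone) and the others were not called (median -0.42; camera, adjusted p = 3.52e-08; adjusted p = 0.408 with an estimated correlation). The cyclin E2 gene Ccne2 fell 2.02-fold and the replication licensing gene Cdc6 1.64-fold. Cholesterol biosynthesis and uptake genes fell, with 8 of 16 lower and the others not called (camera, adjusted p = 0.00758; adjusted p = 0.561 with an estimated correlation), among them Lss (1.43-fold) and Msmo1 (1.41-fold).

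Hypoxia and glycolysis genes rose in ICAT cells, with 17 of 23 higher and the others not called (median log2 difference 0.49; camera, adjusted p = 3.03e-08; adjusted p = 0.378 with an estimated correlation). The aldolase gene Aldoc rose 5.04-fold, the enolase gene Eno2 3.06-fold, Pfkp 2.45-fold and Ndrg1 2.42-fold. Unfolded protein and integrated stress response genes rose, with 9 of 23 higher and 1 lower (11 and 2 adjusted over the list alone; camera, adjusted p = 0.00254; adjusted p = 0.604 with an estimated correlation). The lipoprotein receptor gene Vldlr rose 6.54-fold and Ddit3, which encodes CHOP, 2.46-fold, and the mitochondrial serine hydroxymethyltransferase gene Shmt2 fell 1.79-fold. Without ICAT replicate 3 the list was not called (camera, adjusted p = 0.0766).

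Fibroblast markers rose in ICAT cells, with 9 of 12 higher and 1 lower (median log2 difference 0.95; camera, adjusted p = 4.5e-05; adjusted p = 0.225 with an estimated correlation). Pdgfra rose 4.04-fold, Postn 3.87-fold and the collagen genes Col1a1 and Col1a2 3.63-fold and 2.73-fold. Matrix remodelling enzymes and inhibitors rose along with them, with 13 of 23 higher and 3 lower (14 and 3 adjusted over the list alone; camera, adjusted p = 0.000132; adjusted p = 0.225 with an estimated correlation). The cross-linking enzyme genes Loxl1 and Lox rose 5.19-fold and 3.76-fold, and Timp3, which encodes an inhibitor of metalloproteinases, rose 2.82-fold. Mesenchymal and EMT genes rose, with 11 of 20 higher and 3 lower (11 and 4 adjusted over the list alone; camera, adjusted p = 0.0246; adjusted p = 0.408 with an estimated correlation), among them Tgfbi and Mmp2 (3.56-fold each) and the fibronectin gene Fn1 (2.46-fold). Wnt pathway components rose, with 19 of 48 higher and 4 lower (19 and 5 adjusted over the list alone; camera, adjusted p = 0.00907; adjusted p = 0.225 with an estimated correlation), with the receptor genes Fzd6 and Fzd1 2.42-fold and 1.97-fold higher. That call was lost with the stricter filter (adjusted p = 0.0753). The members that rose include receptors and ligands as well as the antagonist gene Sfrp2 (at least 1.49-fold) and the co-repressor gene Tle2 (1.71-fold).

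The other lists were not called in ICAT cells. Integrins and basement membrane genes had 8 of 24 higher and 3 lower (8 and 4 adjusted over the list alone; camera, adjusted p = 0.363), and semaphorin, ephrin and axon guidance genes 13 of 33 higher and 5 lower (adjusted p = 0.185). Immediate-early and MAPK feedback genes had 9 of 26 higher and 6 lower (camera, adjusted p = 0.926), with Egr1 3.03-fold higher and Dusp4 2.22-fold lower. YAP/TEAD target genes had 8 of 22 higher and 6 lower (camera, adjusted p = 0.591), and TGF-beta and BMP response genes 7 of 25 higher and 4 lower (adjusted p = 0.296). Notch pathway genes had 6 of 17 higher and 1 lower (6 and 2 adjusted over the list alone; camera, adjusted p = 0.367), and Hedgehog pathway genes 5 of 14 higher and 2 lower (adjusted p = 0.367). Stem and tumour-initiating cell markers had 6 of 17 higher and 3 lower (camera, adjusted p = 0.443), and p53 target genes 6 of 16 higher and 3 lower (6 and 4 adjusted over the list alone; adjusted p = 0.443). Epithelial junction and keratin genes had 3 of 23 higher and 2 lower (2 and 2 adjusted over the list alone; camera, adjusted p = 0.926). Ductal and pancreatic progenitor genes had 4 of 16 higher and 1 lower (adjusted p = 0.367), and acinar cell genes 1 of 12 higher (adjusted p = 0.926). None of 11 endocrine and neuroendocrine genes was called by limma (camera, adjusted p = 0.625; fry, adjusted p = 0.361). Counts given without a second pair were the same adjusted over the list alone.

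**Figure D3:**
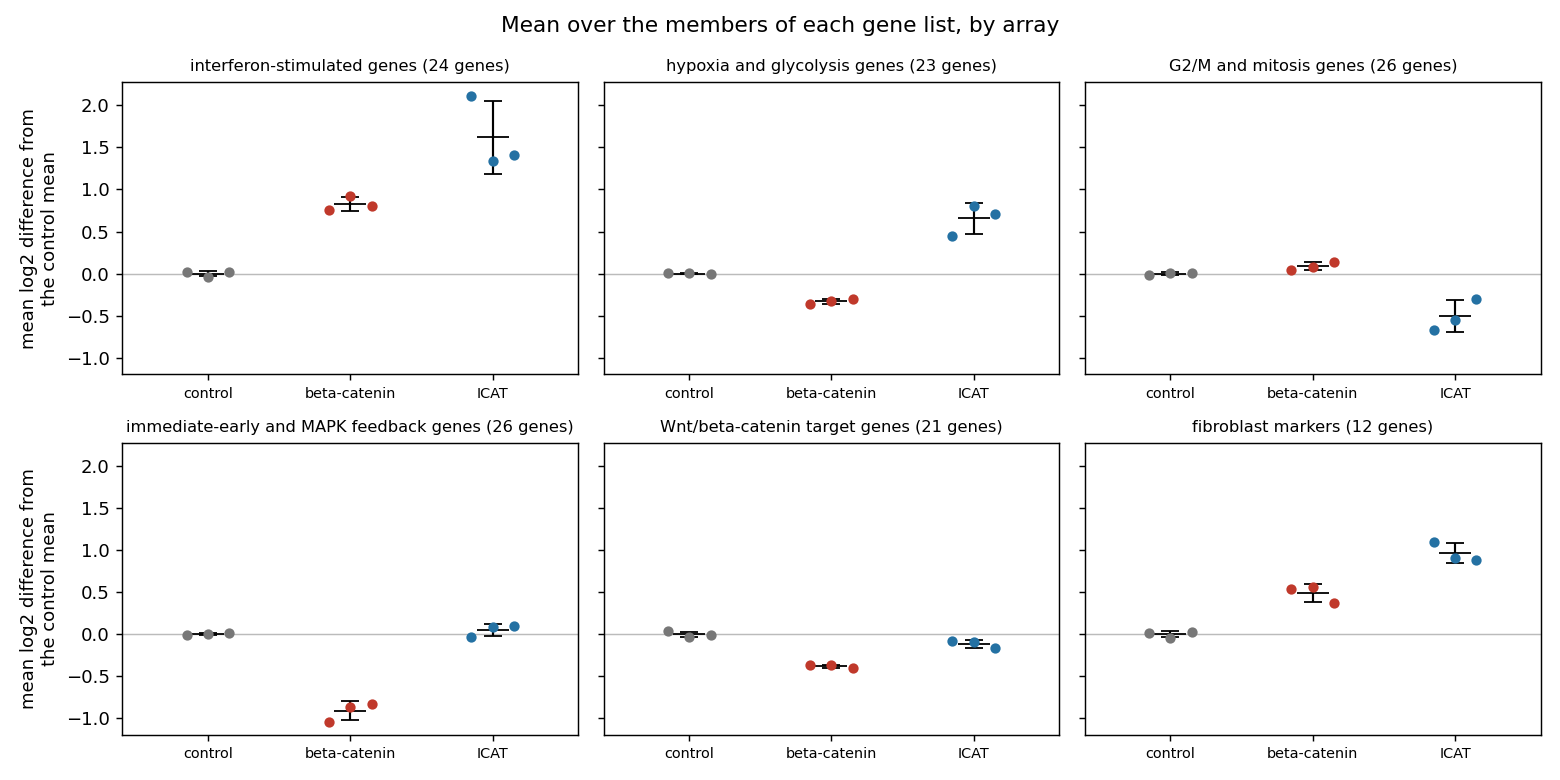
Mean over the members of 6 gene lists of each array's log2 difference from the control mean (vertical axes, log2 units), for control, beta-catenin and ICAT cells; points are arrays, horizontal bars are means and error bars are SD (n = 3). The interferon-stimulated genes lie at 2.12, 1.33 and 1.41 on the ICAT arrays and between 0.758 and 0.925 on the beta-catenin arrays.

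Beta-catenin cells against ICAT cells. This comparison sets the activator of the pathway against its inhibitor and uses the control arrays only for the estimate of spread, the choice of probe sets and the filter. Sprr1b was at least 23-fold higher in beta-catenin than in ICAT cells (adjusted p = 1.44e-09), the amino acid transporter gene Slc6a15 12.8-fold, the selectin gene Selp 11.8-fold, Nrep 9.92-fold and Dclk1 8.16-fold. Mmp13 was at least 29.4-fold lower (4.35 ± 0.0858 against 9.88 ± 0.529, SD, n = 3, adjusted p = 5.59e-09), Dkk2 45.7-fold, Slc14a1 30.7-fold, Bhlhb9 at least 16.3-fold and Bmp2 20-fold. Of the known targets, Lef1 was 1.55-fold higher (adjusted p = 0.000245), Myc 1.25-fold higher (adjusted p = 0.00154) and Ccnd1 2.42-fold lower (adjusted p = 2.30e-07). Ccn1 was 3.05-fold higher, and all of its other probe sets were higher too. In all, 6155 genes passed (limma), 3429 higher and 2726 lower in beta-catenin cells, and 605 of them differed at least 2-fold, 227 higher and 378 lower.

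Hypoxia and glycolysis genes were lower in beta-catenin than in ICAT cells in 20 of 23 cases and higher in 2 (median log2 difference -0.98; camera, adjusted p = 3.52e-10; adjusted p = 0.356 with an estimated correlation), with Aldoc 5.65-fold, Eno2 4.57-fold, Slc2a1 3.94-fold and Adm 3.79-fold lower. Immediate-early and MAPK feedback genes were lower in 20 of 26 cases and higher in 2 (21 and 2 adjusted over the list alone; camera, adjusted p = 8.93e-10; adjusted p = 0.337 with an estimated correlation), with Etv5 9.15-fold, Spry4 7.27-fold and Egr1 4.82-fold lower. G2/M and mitosis genes were higher in 24 of 26 cases (25 adjusted over the list alone; camera, adjusted p = 4.92e-10; adjusted p = 0.472 with an estimated correlation) and G1/S and DNA replication genes in 17 of 25 (adjusted p = 3.17e-06; adjusted p = 0.556 with an estimated correlation), the others not being called. Kif11 was 1.98-fold higher and Prim1 1.99-fold. Interferon-stimulated genes were lower in 17 of 24 cases (19 adjusted over the list alone) and otherwise not called (camera, adjusted p = 2.96e-06; adjusted p = 0.472 with an estimated correlation), with Usp18 3.72-fold and Ifit3 3.15-fold lower.

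Integrins and basement membrane genes were lower in beta-catenin than in ICAT cells in 13 of 24 cases (14 lower and 1 higher adjusted over the list alone; camera, adjusted p = 7.47e-05; adjusted p = 0.337 with an estimated correlation), with Itgb8 at least 9.02-fold and Itga6 2.86-fold lower. Matrix remodelling enzymes and inhibitors were lower in 13 of 23 cases and higher in 6 (15 and 6 adjusted over the list alone; camera, adjusted p = 0.00315; adjusted p = 0.338 with an estimated correlation), with Mmp3 18.8-fold and Mmp10 8.98-fold lower. Beside them, fibroblast markers were lower in 6 of 12 cases and higher in 3 (7 and 3 adjusted over the list alone; camera, adjusted p = 0.106), with Col1a2 7.16-fold lower. Cholesterol biosynthesis and uptake genes were higher in 11 of 16 cases and lower in 1 (12 and 1 adjusted over the list alone; camera, adjusted p = 0.0028; adjusted p = 0.593 with an estimated correlation), with Idi1 1.81-fold and Sqle 1.64-fold higher. Unfolded protein and integrated stress response genes were lower in 11 of 23 cases (12 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00315; adjusted p = 0.593 with an estimated correlation), with Vldlr 4.62-fold lower, and this call was lost without ICAT replicate 3 (adjusted p = 0.0674). Semaphorin, ephrin and axon guidance genes were lower in 14 of 33 cases and higher in 7 (15 and 7 adjusted over the list alone; camera, adjusted p = 0.0466; adjusted p = 0.337 with an estimated correlation), with Sema7a 6.53-fold and Slit2 4.87-fold lower. That call was lost under 6 of 18 other settings, among them those without control replicate 1, ICAT replicate 1 or ICAT replicate 3 (adjusted p up to 0.0989), and its median of -0.02 ranged from -0.13 to 0.03.

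The remaining lists were not called between beta-catenin and ICAT cells. Wnt/beta-catenin target genes had 3 of 21 higher and 6 lower (camera, adjusted p = 0.131), Wnt pathway components 12 of 48 higher and 6 lower (adjusted p = 0.932) and YAP/TEAD target genes 10 of 22 higher and 5 lower (adjusted p = 0.218). MHC class I and antigen processing genes had 1 of 12 higher and 5 lower (camera, adjusted p = 0.147), and NF-kB and inflammatory cytokine genes 3 of 26 higher and 8 lower (adjusted p = 0.069). Mesenchymal and EMT genes had 5 of 20 higher and 9 lower (5 and 10 adjusted over the list alone; camera, adjusted p = 0.283), and epithelial junction and keratin genes 2 of 23 higher and 6 lower (adjusted p = 0.343). Notch pathway genes had 1 of 17 higher and 6 lower (1 and 7 adjusted over the list alone; camera, adjusted p = 0.0876), and Hedgehog pathway genes 7 of 14 higher and 4 lower (adjusted p = 0.427). TGF-beta and BMP response genes had 9 of 25 higher and 7 lower (11 and 7 adjusted over the list alone; camera, adjusted p = 0.397), and p53 target genes 4 of 16 higher and 3 lower (5 and 3 adjusted over the list alone; adjusted p = 0.606). Stem and tumour-initiating cell markers had 5 of 17 higher and 5 lower (5 and 6 adjusted over the list alone; camera, adjusted p = 0.783), and ductal and pancreatic progenitor genes 2 of 16 higher and 4 lower (3 and 4 adjusted over the list alone; adjusted p = 0.397). Acinar cell genes had 1 of 12 higher and 1 lower (camera, adjusted p = 0.967), endocrine and neuroendocrine genes 2 of 11 higher (adjusted p = 0.922), and immune and endothelial markers 3 of 13 lower (adjusted p = 0.0731). Counts given without a second pair were the same adjusted over the list alone.

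Across the 3 comparisons camera with its preset correlation called 5, 12 and 10 of the 27 lists, in the order given above. With an estimated correlation it called 0 in each (1, 5 and 3 at an unadjusted p of 0.05). The test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 18, 20 and 19 lists. Median, mean and camera's direction did not all have one sign for some lists that were not called. In beta-catenin against control these were G1/S, mesenchymal, matrix remodelling, acinar, ductal, endocrine and stem cell genes. In ICAT against control they were YAP/TEAD, epithelial, immune and endothelial, and immediate-early genes, and between the transfected lines acinar, endocrine and stem cell genes.

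Genes called in both transfected lines. A gene under the control of beta-catenin would be expected to move in opposite directions in the 2 lines. Of 3078 genes called in both, 552 did so and 2526 moved the same way, 1534 of them up and 992 down. Mmp13 fell at least 14.4-fold with beta-catenin and rose 2.04-fold with ICAT, the integrin gene Itgb8 fell at least 3.67-fold and rose 2.45-fold, Bnc1 fell at least 2.65-fold and rose 3.38-fold, and Wfdc2 fell 3.56-fold and rose 2.65-fold. Slc6a15 rose 5.43-fold with beta-catenin and fell 2.36-fold with ICAT, and the plakophilin gene Pkp2 rose 4.83-fold and fell 1.59-fold. Tubb2b rose at least 15.9-fold with beta-catenin and at least 11.8-fold with ICAT, and Ptx3 17.3-fold and 10.1-fold. Apoc2 fell 22.2-fold and 22.1-fold, Inpp4b 4.77-fold and 4.72-fold, and Calcrl at least 3.28-fold in each. Among genes changed at least 2-fold in both lines, 208 moved the same way and 14 in opposite directions.

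Independent lists of these sizes would share 990.8 genes in the same direction and 989.5 in opposite directions. Comparisons with the same control arrays are not independent, so these counts are not what lines that merely differ would give. Unchanged groups simulated against the same control arrays gave a mean of 0 for either count. That value lies near 0 by construction, because hardly any unchanged gene is called. It therefore does not show how shared controls divide the genes called in both lines. The opposite-direction count depended on each control array, being 316 without control replicate 1, 339 without control replicate 2 and 319 without control replicate 3, and it was 1015 with array weights. The log2 differences of the lines correlated across genes at 0.484 (genes are not independent replicates), against a simulated 0.501 for unchanged groups sharing the controls, a value near 0.5 by construction. Their covariance was 0.096 against a simulated 0.00426, a difference of 0.0917. Because 3 control arrays cannot be split into parts of at least 2, part of the excess of genes moving the same way may come from the shared controls.

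**Figure D4:**
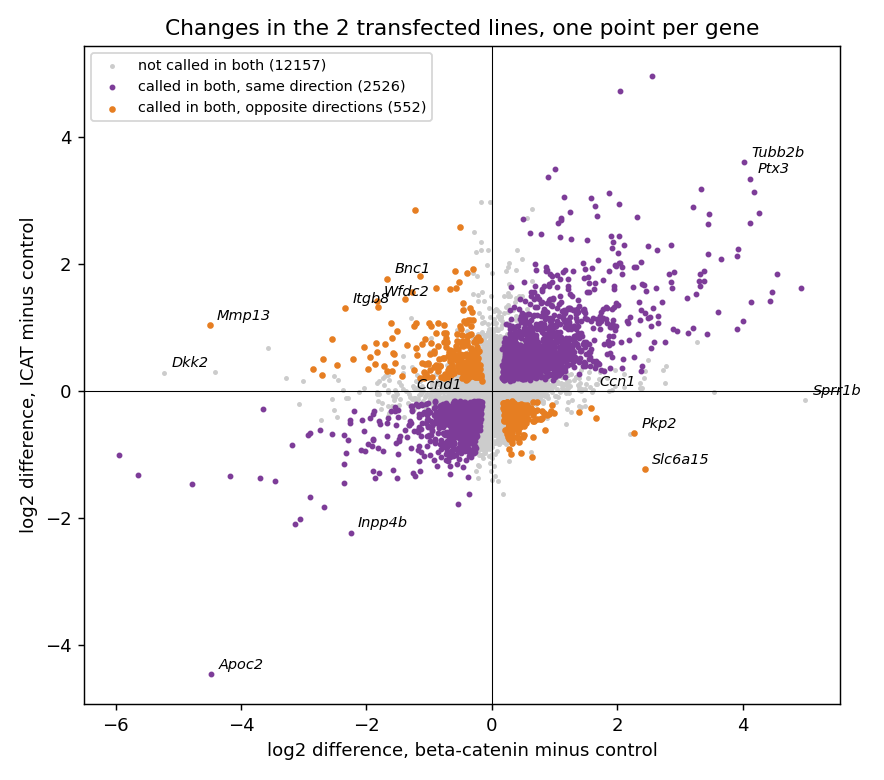
Log2 difference of each of the 15235 tested genes between beta-catenin and control cells (horizontal axis) and between ICAT and control cells (vertical axis), from means of 3 arrays per group. Purple points passed the limma threshold in both lines in the same direction (2526 genes), orange points in opposite directions (552 genes), and grey points did not pass in both.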

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

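Chosen after the results were seen were the tests of the shared controls, of opposite action and of batches for the genes that moved the same way, the test of immune cells for the interferon genes, and the test of chance order for neighbouring genes. All other tests in this part were written before.

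Hypoxia and glycolysis genes stood out because the list was called lower in beta-catenin cells and higher in ICAT cells (camera, adjusted p = 0.00116 and 3.03e-08; adjusted p = 0.565 and 0.378 with an estimated correlation). The median log2 difference between beta-catenin and ICAT cells was -0.979 (camera, adjusted p = 3.52e-10; adjusted p = 0.356 with an estimated correlation). Of 23 members 8 were called lower in beta-catenin and higher in ICAT cells, among them Eno2 and Vegfa, and 2 were called higher in both, among them Pfkp. Probe sets without a gene name, which no comparison of the report uses, also carried signal: limma called 681 for beta-catenin against control, 586 for ICAT against control and 772 for beta-catenin against ICAT, out of 5249 that passed the filter.

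Genes called in both lines mostly moved the same way, 2526 of them, such as Apoc2, Tubb2b and Ptx3, and 552 moved in opposite directions. Independent lists would give 989.5 opposite genes, but comparisons with the same controls are not independent. Spread of the shared control arrays alone does not account for the whole of the movement in the same direction. The log2 differences of the lines had a covariance of 0.096 across genes, against at most 0.00468 in 100 simulations of unchanged groups. These simulations give no value for lines that differ from one another. Opposite action of beta-catenin and ICAT on part of the genes stays open, since the shared controls lower the opposite count. A separate batch of the control cells, by handling or culture, cannot be told apart from a difference of the control line itself. The labels name no batch, so 0 batches are known to hold both kinds of array, and all 3 groups were transfected.

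Interferon-stimulated genes were higher in ICAT cells, among them Usp18, Rtp4 and Ifit1 (camera, adjusted p = 3.04e-13; adjusted p = 0.27 with an estimated correlation), and 14 of 24 were higher in beta-catenin cells too (camera, adjusted p = 0.000141; adjusted p = 0.563 with an estimated correlation). Immune or endothelial cells in the cultures would be expected to bring their markers, but 0 were called higher by limma (1 at an unadjusted p of 0.05) and their median log2 difference was 0.00399. Fibroblast markers did rise in ICAT cells (9 of 12, median log2 difference 0.95; camera, adjusted p = 4.5e-05; adjusted p = 0.225 with an estimated correlation), and whether this and the interferon genes have a common source was not tested. An aberrant array or the scaling of the arrays is an unlikely source, because the median of the list was at least 1.49 whichever array was left out (camera, highest adjusted p = 1.36e-11; adjusted p = 0.27 with an estimated correlation on all arrays) and at least 1.76 under other scalings. An interferon response of the cells, or a difference between the lines that arose before or after transfection, stays possible, and the labels hold nothing that separates these.

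Neighbouring genes moved together. In the order of the gene table, log2 differences of adjacent genes correlated at 0.197 in beta-catenin and 0.0719 in ICAT cells (genes are not independent replicates), against at most 0.0234 and 0.0255 in shuffled orders, so chance order does not account for it. Co-regulation of directly adjacent genes only would not reach 20 positions, where the correlations were 0.0755 and 0.0467 (at most 0.03 and 0.0269 when shuffled). Gains or losses of chromosome segments in the lines could give modest shifts over long runs of genes, and without genes changed at least 2-fold the correlations at 20 positions were 0.0844 and 0.031 (at most 0.0265 and 0.0242 when shuffled). DNA copy number was not measured in the values used here, so segments remain a hypothesis. The correlations were taken over all chromosomes together. They do not separate segments from other causes that reach over many neighbouring genes or a whole chromosome.

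Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For genes the real grouping alone (1 of 10) reached 5321, 5670 and 6155 calls in the order of the comparisons, with 0 as the highest other count. For lists called by camera, 2 of 10 splits reached the real 5 for beta-catenin against control (highest other 7), 1 of 10 the real 12 for ICAT against control (highest other 9), and 3 of 10 the real 10 for beta-catenin against ICAT (highest other 13). Of 100 ways to divide the 9 arrays into 3 groups, 1, the real one, reached 2526 genes in the same direction (highest other 1735, a division that takes the 3 beta-catenin arrays as the shared group and mixes control with ICAT arrays), and 1, the real one, reached 552 in opposite directions (highest other 0), which excludes only that a random division would give these counts. All other divisions mix arrays of lines that differ, which keeps part of the real difference and widens the spread within groups, so they give no count for unchanged groups.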

How the results depend on the processing

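No test in this part was chosen after the results were seen. Of the list results under other settings 1522 kept their side of the threshold, 61 newly passed and 37 no longer did. For the named genes these counts were 6683, 6 and 107. Of the 37 list results lost, 27 came from camera with an estimated correlation, under which 0 lists were called in each comparison. Of the 61 gained, 30 came from fry. The 1522 include lists that were called in neither fit. No result that passed in either fit was reversed, taking the list test's direction for lists. The median of the axon guidance list between beta-catenin and ICAT cells did change sign, ranging from -0.13 to 0.03. Apart from the 2-fold threshold, every setting kept at least 79.8 percent of calls, none shifted the median difference of all genes by over 0.0456, and 11 shared calls changed direction, with the mean of all probe sets. With array weights 8324 genes were called for beta-catenin against control and 1015 in opposite directions. The lowest weights fell on ICAT replicates 3 and 1 (0.217 and 0.468). Leaving out ICAT replicate 3 also raised the beta-catenin count, to 6218. With only the 6 arrays compared, 6658, 5079 and 5292 genes were called in the order of the comparisons. The main fit gave 5321, 5670 and 6155. It shares its estimate of spread over all groups, although the median SD was 0.0567 in control, 0.0746 in beta-catenin and 0.121 in ICAT cells. Leaving out the ICAT arrays raised the beta-catenin count, and both comparisons with ICAT lost calls in their own fits. Which line had more genes called against control therefore depended on the arrays that gave the spread. The cause was not tested further. With a 2-fold threshold the counts were 704, 448 and 605, by construction. Leaving out each array gave 4285 to 6218 genes for beta-catenin against control, 4587 to 6153 for ICAT against control, 5182 to 6981 for beta-catenin against ICAT, 316 to 789 in opposite directions and 1956 to 2848 in the same direction, with fewer samples. The other Ctnnb1 probe sets gave 0.2631 (limma, adjusted p = 0.0904) and 0.1793 (adjusted p = 0.0744) for beta-catenin against control, in a fit over all probe sets in which the brightest probe set did not pass either (adjusted p = 0.0672). A block for the replicate number gave 5524, 5853 and 6389 genes. Deviations from the group means correlated highest for a pair of the same number, beta-catenin 3 with ICAT 3 (0.41). Control 3 correlated with these arrays at 0.121 and 0.175. However, beta-catenin 1 correlated best with ICAT 2 (0.333), and beta-catenin 2 with ICAT 2 gave -0.129. Whether a number marks a shared day or culture thus stays open. The test of RNA quality and its alternative were not run, because Affymetrix control probe sets are not among the probe sets used here. Dim probe sets limit what arrays can show, since values near background are compressed.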

Other observations

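The tests of 3 added gene lists, of Xist and of runs of neighbouring genes were chosen after the results were seen. Ribosome biogenesis and RNA polymerase I genes, gathered by symbol pattern, fell in ICAT cells, with 43 of 56 lower and 1 higher (median log2 difference -0.60; camera, unadjusted p = 8.35e-18; p = 0.0702 with an estimated correlation). Nop16 fell 3.46-fold, Taf1d 3.09-fold, the polymerase subunit gene Polr1b 2.56-fold and Nolc1 2.24-fold (n = 3 per group). In beta-catenin cells 19 of these genes fell and 3 rose (camera, unadjusted p = 0.00621; p = 0.51 with an estimated correlation). Between beta-catenin and ICAT cells 37 were higher and 3 lower (unadjusted p = 1.17e-09; p = 0.171 with an estimated correlation). Nop16 and Taf1d, members of this list, had already been seen among the largest decreases in ICAT cells. The camera p for ICAT cells is therefore not independent of that observation. Membership rests on the symbol alone.

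Complement genes had 4 of 9 members higher and 1 lower in ICAT cells (camera, unadjusted p = 0.0118; p = 0.189 with an estimated correlation) and 4 higher in beta-catenin cells (unadjusted p = 0.117). C1s1 rose 11.2-fold in ICAT and 2.01-fold in beta-catenin cells, C1ra 7.47-fold and 3.13-fold, and the clusterin gene Clu 3.69-fold and 1.82-fold. NRF2 antioxidant response genes went both ways, with 10 of 26 higher and 5 lower in beta-catenin cells (camera, unadjusted p = 0.191) and 10 higher and 9 lower in ICAT cells (unadjusted p = 0.18).

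Xist, the RNA that silences an X chromosome, was 11.9-fold, 12.9-fold and 7.16-fold higher in ICAT than in control cells by its 3 probe sets (limma, adjusted p from 1.33e-09 to 7.88e-08), and at least 3.09-fold, at least 1.12-fold and 2.35-fold lower in beta-catenin cells. The 9 probe sets of 3 Y-linked genes reached at most 5.09 on any array. In runs of 41 neighbouring genes, that from Pwwp3b to Smc1a had 29 genes called higher in beta-catenin cells and a median log2 difference of 0.83, with a mean of 0.611 against at most 0.315 in 1000 shuffled orders. The run from Wdr13 to Uxt was higher in both lines, with 29 genes called in beta-catenin cells (median 0.54) and 28 in ICAT cells (median 0.39). The runs were not sorted by chromosome. Whether they, or the correlation of neighbouring genes, relate to the difference in Xist was not tested.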
